A study of Homo sapiens with 55 samples.

How the data were processed

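Total RNA from tumour tissue was extracted with Trizol, treated with DNase I, turned into biotinylated cRNA and hybridised to Affymetrix human genome U133 arrays (A chip), per the labels' protocols. Each sample had 1 array. The 55 arrays held 12 cellular mesoblastic nephromas (CMN), 2 infantile fibrosarcomas (IFS), 15 Wilms tumours of favourable histology (WT), 10 rhabdoid tumours (RT) and 16 clear cell sarcomas of the kidney (CCSK). Groups and replicate numbers came from the sample titles. CMN and IFS were combined as 1 class of 14 arrays, as in the study's design text, so that 4 classes were compared.

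The values used were the deposited probe set signals of the series' value table. They were on a log2 scale, as judged from the deposited values themselves, which ran from 3.35 to 14.31. The method of background correction, summarisation and normalization was not given in the sources used here. Array medians lay between 6.10 and 6.23 across the deposited arrays, and no further normalization was applied. No pseudocount was needed. Differences below are differences of mean log2 signal, and a fold is 2 raised to that difference, which understates true ratios for dim probe sets.

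The table held 22215 probe sets. Gene symbols came from the platform annotation supplied with the table and were checked through Entrez identifiers, of which 19053 matched and 0 led to a changed symbol. Of the probe sets, 19065 had 1 symbol, 1043 had several and 2107 had none; those with several or none were not used for named genes. A further filter left out 52 probe sets of XIST, TSIX and genes on the Y chromosome, so that no sample's sex could be read from any result. The remaining probe sets stood for 11939 genes. A probe set was kept if it exceeded its array's 25th percentile in at least 10 arrays, and each gene was represented by the kept probe set with the highest mean over all 55 arrays, a rule that does not use the groups. This left 10324 genes for testing. IGF2, one of the genes chosen for display, was not analysed here because it had no probe set of its own under these rules.

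Expression was compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. All 55 arrays entered 1 fit with 4 classes, which left 51 residual degrees of freedom per gene. IFS and CMN were compared in a fit with 5 groups and 50 residual degrees of freedom, because 2 IFS arrays give little information on spread by themselves. With 1 of them left out, the other is assumed to vary like the other groups. P-values were adjusted over all genes tested by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05 together with a fold of at least 2. A gene belonged to the signature of a class if it was called in the same direction against each of the other 3 classes. Every adjusted p printed for a gene is limma's. An error printed with a log2 difference is its standard error (SE) from the fit; an error printed with a class mean is the standard deviation (SD) between arrays.

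For 33 lists of genes, taken from textbook knowledge and not from these samples, limma's camera compared each list with all other genes, with a preset correlation between genes of 0.01. The contrasts were each class against the mean of the other 3 class means, and IFS against CMN. The 165 tests were adjusted together. Camera was also run with the correlation estimated from the data, and fry was run beside it. Of the 883 list entries, 765 were on the array. A list member counted as higher or lower at an adjusted p below 0.05 with no minimum fold. The counts are given over all genes tested and adjusted over the list alone. Such passes were common among all genes, so a count by itself does not set a list apart.

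Genes were named by a fixed rule. It took 11 index genes (NTRK3, ETV6, SMARCB1, WT1, IGF2, EGFR, PDGFRA, PDGFRB, KIT, FGFR1 and IGF1R). It took, per signature, the 10 higher and 10 lower genes (5 and 5 for the signatures of RT, CCSK and Wilms tumour) with the largest value of the smallest absolute log2 difference over the 3 pairwise comparisons. It took the 3 members with the largest change of each called list, or 6 for the receptor tyrosine kinases, their ligands, the MAPK genes and the PI3K genes in CMN/IFS, and the 5 largest called genes each way for IFS against CMN. The groups, tests, thresholds, lists, naming rule and most of the alternative settings were fixed before the data were examined.

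The fitting code was checked on simulated data in which known genes among the 10324 were shifted. For the CMN/IFS signature, 98.5% of genes changed by a log2 value of 1.5 were recovered, 98.5% at 2 and 100% at 3, with 0 false calls. For IFS against CMN the shares were 91.0%, 97.0% and 98.5%, with 3 false calls. The simulated genes varied independently of each other, each with the same spread in every group. These shares therefore check the code and do not give the share of real changes found, least of all with 2 IFS arrays.

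Arrays were compared before averaging. No 2 arrays held identical values, and the highest correlation between any 2 was 0.987. Replicate numbers recur across groups. Over 67 same-numbered pairs of arrays of different classes the mean correlation of residuals was 0.0314, and over differently numbered pairs it was -0.00212. This difference was not tested. The numbers were not treated as pairing, and a fit with them as a block was run as an alternative. A check of RNA quality from the ratio of 3′ to 5′ control probe sets had been planned; the table used here holds 0 control probe sets, so it was not computed. The SD of each array's log2 values, chosen later, served in its place; it ranged from 1.52 to 1.82 and did not differ detectably by class (two-sided permutation test, 100000 permutations, p = 0.49). No batch, date or array lot was used here. P-values measure the spread between these samples, which the labels number separately without saying more about their donors. For arrays no count depth exists, and the number of arrays limits the precision.

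The alternatives tried were quantile normalization, median centring, other filters on dim probe sets, other ways to represent a gene, leaving out probe sets whose names end in _x_at or _s_at (designs that can match more than 1 transcript), other variance models, array weights, the replicate number as a block, other thresholds, fits with only the groups compared, CMN alone, and each array left out in turn. Covariates for array SD, the immediate early genes and the macrophage genes, a fit without the array of smallest SD, a split of the CMN/IFS arrays into 3 separate sets, and the gene lists with each array left out in turn, were added after the data had been seen. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.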

Results

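Expression was measured on 55 arrays of tumours that arise mainly in young children. Cellular mesoblastic nephroma (CMN), a spindle cell tumour of the kidney, and infantile fibrosarcoma (IFS), its soft tissue counterpart, made up 1 class of 14 arrays (CMN/IFS). The other classes were rhabdoid tumour (RT, 10 arrays), clear cell sarcoma of the kidney (CCSK, 16 arrays) and Wilms tumour (WT, 15 arrays), a tumour that resembles the developing kidney. All 15 Wilms tumours are labelled as favourable histology, so results on WT cover that histology only. The study's title names receptor tyrosine kinase activation in CMN/IFS, and its design text names pathways and treatment targets in RT. The comparisons below therefore set CMN/IFS against each other class, each class against all 3 others, and IFS against CMN. A class given as higher or lower without a named partner was set against the mean of the other 3 class means, so it need not be the highest or lowest of the 4.

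The arrays grouped by class. The first principal component, with 24.04% of the variance over 10324 genes, set CCSK apart from the other classes, and the second, with 17.5%, set CMN/IFS apart from WT. Both IFS arrays lay among the CMN arrays. A later component, with 5.75% of the variance, followed the SD of the array's values (Pearson r = 0.904, as a description of this component), and this SD did not differ detectably between classes.

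**Figure D1:**
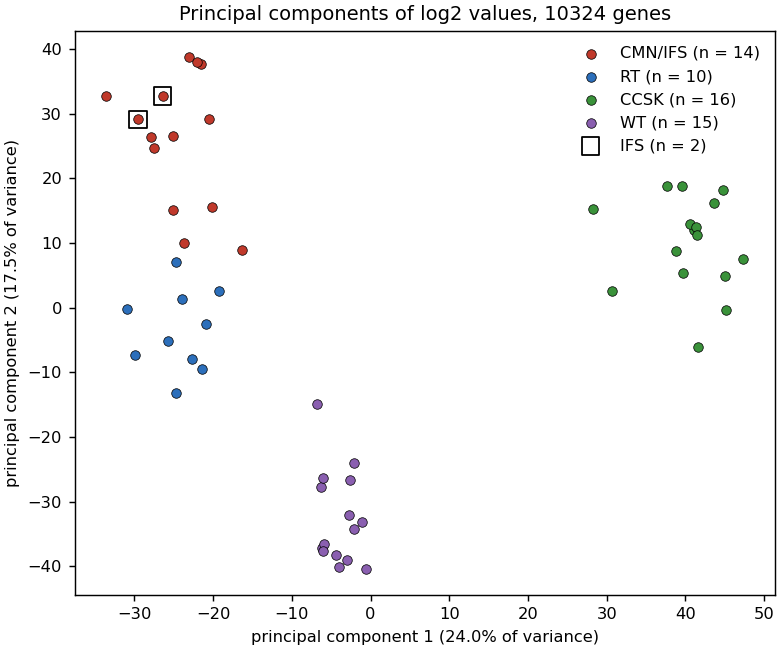
Each point is 1 array, placed by the first (24.04% of variance) and second (17.5%) principal components of log2 values over 10324 genes, in arbitrary component units; colours mark the 4 classes and squares mark the 2 IFS arrays. The 16 CCSK arrays lie apart on the first component, and the 2 IFS arrays lie among the other 12 arrays of their class.

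Genes with known roles in these tumours served as a first look at the classes. SMARCB1, the SWI/SNF subunit whose loss defines RT, was 2.61-fold lower in RT than in the other 3 classes (log2 difference -1.38 ± 0.12 SE, adjusted p = 8.26e-14). Its mean was 7.10 ± 0.18 (SD, n = 10) in RT, 8.34 ± 0.48 (n = 14) in CMN/IFS, 8.23 ± 0.30 (n = 16) in CCSK and 8.88 ± 0.33 (n = 15) in WT. WT1, a transcription factor of the nephron progenitor, was higher in WT by 4.42 ± 0.32 (adjusted p = 9.25e-17), with a mean of 9.83 against 6.64, 5.07 and 4.51 in CMN/IFS, RT and CCSK. In RT, 1 array read 9.57 and the next 5.05. The CMN/IFS arrays ran from 4.65 to 9.98 (SD 1.57) and so overlapped the WT arrays, of which the lowest read 8.62. ETV6, the gene whose fusion to NTRK3 is the textbook rearrangement of CMN and IFS, was higher in CMN/IFS by 0.19 ± 0.06 (adjusted p = 0.00834).

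NTRK3, a receptor tyrosine kinase, was read by 7 probe sets that gave different pictures. Of these, 3 have plain _at names and are called a, b and c here, in the order of their identifiers. The probe set with the highest signal, an _x_at set, was higher in CMN/IFS by 0.41 ± 0.14 (adjusted p = 0.0137), with means of 7.76 in CMN/IFS, 6.99 in RT, 7.90 in CCSK and 7.16 in WT. This call was lost without CMN replicate 2 (0.32, adjusted p = 0.0523). On probe set a the difference was 0.96, and on b it was -0.41. On a, 7 CMN/IFS arrays read between 4.94 and 5.32 and the other 7 between 8.08 and 9.01, while RT ran from 4.66 to 5.34, WT from 4.80 to 5.45 and CCSK from 6.36 to 8.77. The fusion status of the tumours was not analysed here.

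**Figure D2:**
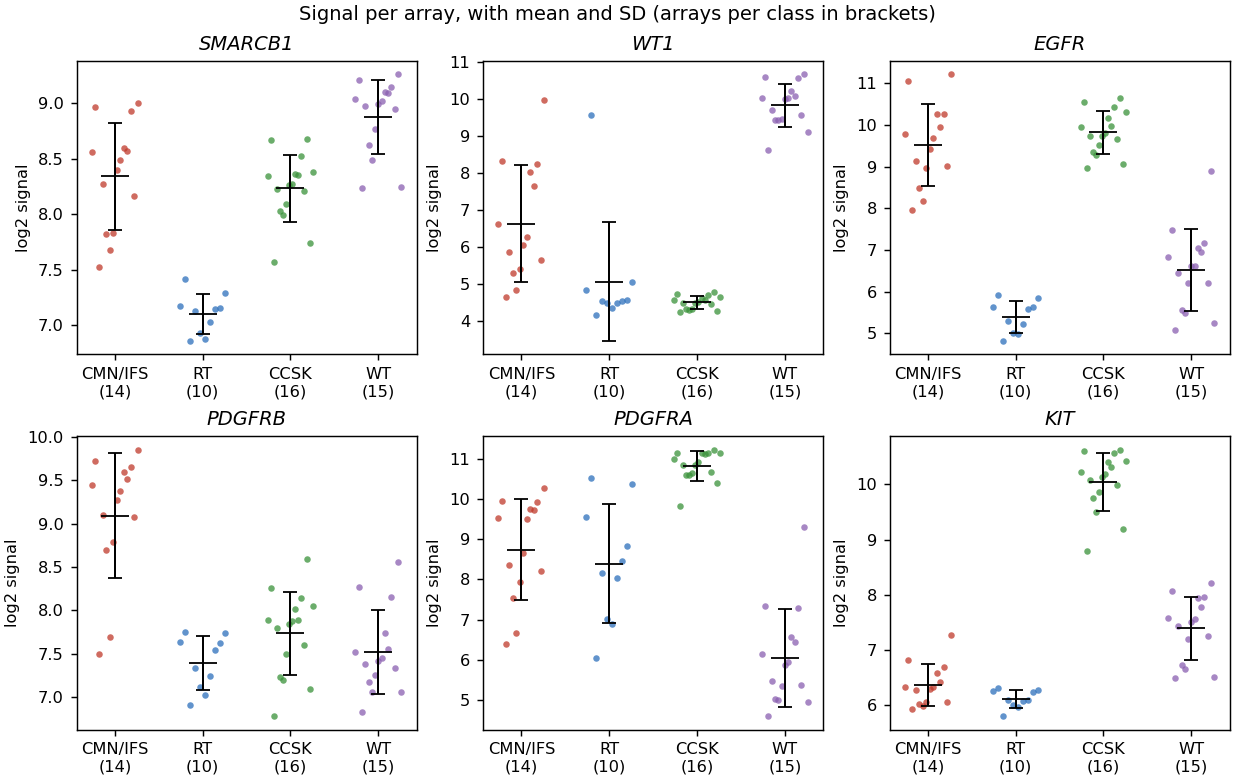
Log2 signal of SMARCB1, WT1, EGFR, PDGFRB, PDGFRA and KIT on each array (points), by class, with the class mean and SD as bars (n = 14, 10, 16 and 15). SMARCB1 is lowest in RT (mean 7.10), WT1 highest in WT (9.83), PDGFRB highest in CMN/IFS (9.09), and PDGFRA and KIT highest in CCSK (10.82 and 10.04).

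In CMN/IFS, 161 genes were higher than in each of the 3 other classes. THBS4, a secreted glycoprotein of tendon matrix, was 17.1-fold higher than the mean of the other classes (log2 difference 4.09 ± 0.31 SE), and TGFBI, a matrix adhesion protein, was 15.9-fold higher (3.99 ± 0.20). The homeobox gene MEOX2 was higher by 4.58 ± 0.43, the collagen gene COL11A1 was higher by 4.32 ± 0.42, and TNMD, a marker of tendon cells, by 3.10 ± 0.38, with an SD of 2.44 between the 14 CMN/IFS arrays. VCAM1, an adhesion molecule (3.71), IFI16, an interferon-inducible DNA sensor (3.83), the immune GTPase GIMAP6 (3.43), the homeobox gene HLX (3.50) and MTUS1, a microtubule-associated protein (3.51), completed the 10 highest under the naming rule. Adjusted p for these 10 genes ran from 3.61e-23 for TGFBI to 2.44e-09 for TNMD.

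Ordered by the smallest of the 3 pairwise differences, the lower genes of CMN/IFS were led by FGFR2, a fibroblast growth factor receptor, at 9.76-fold lower (-3.29 ± 0.26, mean 6.17 against 9.46, 9.37 and 9.53 in RT, CCSK and WT). The FGFR2 value came from an _s_at probe set; without _x_at and _s_at probe sets it was 0.0031 (adjusted p = 0.976), read from a dim probe set with a CMN/IFS mean of 5.90. NR2F1, an orphan nuclear receptor, was lower by a log2 difference of -3.47 ± 0.36, CXADR, a junction protein, by -2.51, UCHL1, a deubiquitinase abundant in neurons, by -2.48, and ODC1, the rate-limiting enzyme of polyamine synthesis, by -2.16. The homeobox genes HOXB6 and HOXC10 (-2.56 and -1.97), the golgin gene GOLGA8A (-1.98), PNMA1 (-1.86) and YBX3 (-1.73) followed. In all, 189 genes formed the CMN/IFS signature, 161 higher and 28 lower. All 3 comparisons share the CMN/IFS arrays; independent lists of the same sizes would share 0.836 higher and 0.427 lower genes by chance, and with the CMN/IFS arrays split into 3 separate sets, 1 per comparison, the signature held 150 genes, 139 of them the same. Without _x_at and _s_at probe sets, which left fewer genes to test, it held 121.

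Receptor tyrosine kinases moved both ways in CMN/IFS. EGFR, the epidermal growth factor receptor, was higher by 2.28 ± 0.24 (mean 9.53 ± 0.99, against 5.39 in RT, 9.82 in CCSK and 6.52 in WT): it was 17.5-fold above RT and 8.03-fold above WT, and differed from CCSK by -0.30 (adjusted p = 0.444). PDGFRB, a platelet-derived growth factor receptor of mesenchymal cells, was 2.91-fold higher (1.54 ± 0.16, adjusted p = 2e-11) and was above each other class by 1.36 to 1.70 on the log2 scale. DDR2, a receptor for fibrillar collagen, was higher by 1.57 ± 0.23, and FGFR1 by 0.83 ± 0.19 (adjusted p = 4.17e-04). KIT, the stem cell factor receptor, and IGF1R, the insulin-like growth factor receptor, were lower by log2 differences of -1.48 ± 0.14 and -1.54 ± 0.23. Neither was lower than in RT: KIT had means of 6.37 in CMN/IFS, 6.12 in RT, 10.04 in CCSK and 7.40 in WT, and IGF1R of 6.63, 6.21, 9.46 and 8.81. PDGFRA differed by 0.32 ± 0.34 (adjusted p = 0.495), an average over classes that lay on both sides of CMN/IFS. Its means were 8.74 in CMN/IFS, 8.39 in RT, 10.82 in CCSK and 6.04 in WT. Of the 43 receptors tested, 10 were higher, 8 lower and 25 did not pass (adjusted over the list alone, 12 and 8), and camera did not call the list (adjusted p = 0.704). EGFR and FGFR1 rested on _s_at probe sets: without _x_at and _s_at probe sets they read 0.09 (adjusted p = 0.116) and 0.34 (adjusted p = 0.165), and for FGFR1 an _x_at probe set gave -0.46. The EGFR probe set used in that setting was flat in RT too (-0.07, adjusted p = 0.306). Whether it responds to EGFR was not tested.

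Among 35 receptor ligands, 9 were higher and 10 lower in CMN/IFS (10 and 10 adjusted over the list alone, camera adjusted p = 0.799). PTN, the growth factor pleiotrophin, was higher by 2.59 ± 0.32, from an _x_at probe set (0.04, adjusted p = 0.7, without such sets). The PTN probe set that took its place was flat in RT too (-0.01, adjusted p = 0.961). Whether it responds to PTN was not tested. The fibroblast growth factors FGF9 and FGF13 (-2.07 and -1.46), the ephrin EFNB2 (-1.52) and the platelet-derived growth factors PDGFA and PDGFC (-1.51 and -1.40) were lower. The means of EFNB2, PDGFA and FGF13 in CMN/IFS were above those in RT, and that of PDGFC above CCSK. Of 28 genes of the PI3K, AKT and mTOR pathway, 5 were higher and 7 lower (5 and 8 adjusted over the list alone, camera adjusted p = 0.595, fry adjusted p = 0.00133). EIF4EBP1, a translation repressor, was higher by 0.75, and PIK3R3 (-0.94), PHLPP1 (-0.76), PIK3CB (-0.68), GSK3B (-0.65) and FOXO3 (-0.47) were lower. Adaptors and negative regulators of these receptors numbered 6 higher and 6 lower of 29 (7 and 8 adjusted over the list alone, adjusted p = 0.718).

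Output and feedback genes of the MAPK pathway, which ERK signalling induces, were higher as a group in CMN/IFS. SPRY4, a feedback inhibitor of receptor signalling, was 8.39-fold higher (3.07 ± 0.15 SE, adjusted p = 3.31e-23), with 11.44 ± 0.44 (SD, n = 14) in CMN/IFS and 8.51, 8.54 and 8.06 in RT, CCSK and WT. Its relatives SPRY2 and SPRY1 were higher by 2.41 ± 0.25 and 2.14 ± 0.19, the ERK phosphatases DUSP6 and DUSP5 by 2.59 ± 0.24 and 2.36 ± 0.27, and the early transcription factor EGR1 by 2.71 ± 0.24. DUSP5 was uneven within CMN/IFS. Some arrays read 6.55 to 7.74, within or below the CCSK range of 6.93 to 8.69, and the others 9.71 to 10.62. Of 25 MAPK output and feedback genes, 13 were higher and 1 lower (15 and 1 adjusted over the list alone). The mean difference was 0.92, and camera called the list (adjusted p = 1.1e-06, and 0.0107 with an estimated correlation). Immediate early genes, which also rise when tissue waits before freezing, moved the same way: 12 of 18 were higher and 0 lower (the same counts adjusted over the list alone, mean 0.81, adjusted p = 5.15e-06, adjusted p = 0.113 with an estimated correlation), with PTGS2, the inducible cyclooxygenase, higher by 2.23 and EGR3 by 1.82. The immediate early mean was uneven within CMN/IFS. CMN replicate 5 read 9.12 and the other arrays 7.14 to 8.56, next to class means of 7.14 in RT, 7.21 in CCSK and 6.78 in WT.

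**Figure D3:**
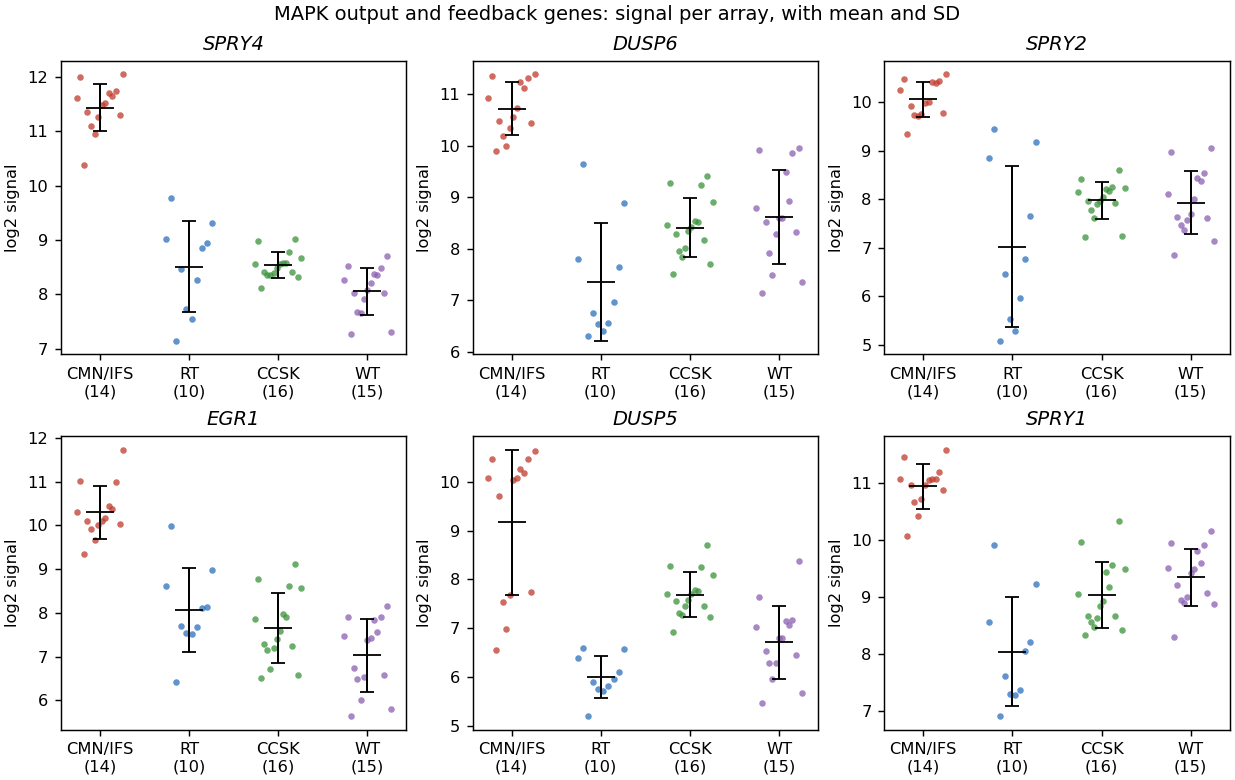
Log2 signal of 6 MAPK output and feedback genes (SPRY4, DUSP6, SPRY2, EGR1, DUSP5 and SPRY1) on each array (points), by class, with the class mean and SD as bars (n = 14, 10, 16 and 15). For SPRY4 the CMN/IFS arrays run from 10.37 to 12.04 and the highest array of any other class reads 9.78. For DUSP5 the CMN/IFS arrays run from 6.55 to 10.62, with none between 7.74 and 9.71, and overlap the other classes.

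Genes of fibroblasts and collagen matrix were the group with the largest mean difference in CMN/IFS. COL11A1, the matrix glycoprotein TNC (3.24 ± 0.38) and COL6A3 (2.86 ± 0.36) led 27 higher and 2 lower genes of 39, with the same counts adjusted over the list alone and a mean difference of 1.25 (camera adjusted p = 5.69e-11, adjusted p = 0.0541 with an estimated correlation). Matrix proteases and their inhibitors were higher for 12 of 19 and lower for 1 (the same adjusted over the list alone, mean 0.83, adjusted p = 7.43e-07, and 0.0011 with an estimated correlation), among them the gelatinase MMP9 (2.85) and the protease inhibitors SERPINE2 (2.50) and SERPINF1 (2.16). Smooth muscle and myofibroblast genes numbered 7 higher and 1 lower of 17 (8 and 2 adjusted over the list alone, adjusted p = 0.0365, adjusted p = 0.433 with an estimated correlation), led by the contractile genes TPM2 (2.73), CALD1 (1.83) and CSRP1 (1.70). The mean of this list was 7.58 in CMN/IFS and 7.53 in RT, and its call was lost without IFS replicate 2 (adjusted p = 0.0715) or CMN replicate 3 (adjusted p = 0.0598). Markers of other cells shifted in the same tumours. Macrophage genes were higher for 14 of 17 and lower for 0 (same adjusted over the list alone, mean 0.77, adjusted p = 9.51e-07, adjusted p = 0.231 with an estimated correlation), such as MRC1 (1.30), CD163 (1.18) and LYZ (1.17). Endothelial genes were higher for 7 of 16 and lower for 1 (same adjusted over the list alone, adjusted p = 0.0266, adjusted p = 0.456 with an estimated correlation). ENG was at 2.25, EMCN at 1.41 and TIE1 at 0.71. Interferon response genes were higher for 15 of 22 and lower for 0 (16 and 0 adjusted over the list alone, adjusted p = 6.12e-04, adjusted p = 0.583 with an estimated correlation). GBP1 was at 1.84, IFI27 at 1.51 and IFIT1 at 1.33. The list mean was uneven within the class (SD 1.19): 4 CMN/IFS arrays read 8.53 to 9.07 and the other 10 read 5.97 to 6.98, next to class means of 6.79 in RT, 6.49 in CCSK and 6.23 in WT.

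Lists of HOX, nephron progenitor, hedgehog, polycomb and proliferation genes were lower in CMN/IFS than in the mean of the other classes. Of 18 HOX genes, 13 were lower and 0 higher (same adjusted over the list alone, mean -0.91, camera adjusted p = 4.96e-07, and 0.039 with an estimated correlation), including HOXB6 and HOXC6 (-2.00). With an estimated correlation the HOX call was lost without CMN replicate 4 (adjusted p = 0.0589) or CCSK replicate 9 (adjusted p = 0.0545). Nephron progenitor genes were lower for 12 of 20 and higher for 2 (13 and 2 adjusted over the list alone, mean -0.60, adjusted p = 1.9e-05, and 0.0107 with an estimated correlation); SALL1, a zinc finger gene of the metanephric mesenchyme, was lower by a log2 difference of -2.62, while MEOX2, a gene of other mesenchyme too, was higher. CMN/IFS was not below RT here, with list means of 6.87 in CMN/IFS, 6.31 in RT, 7.21 in CCSK and 8.88 in WT. SALL1 itself lay near the floor of the signal in both (3.84 and 3.83), so it cannot rank these 2 classes. Hedgehog pathway genes were lower for 4 of 10 and higher for 0 (same adjusted over the list alone, adjusted p = 0.00582, and 0.0451 with an estimated correlation). The receptor PTCH1 was at -1.69 and the targets FOXF1 and FOXF2 at -1.42 and -1.25. The difference came from CCSK: the list mean was 7.86 in CCSK, against 6.51 in CMN/IFS, 6.50 in RT and 6.61 in WT. With an estimated correlation it was lost without CMN replicate 4 (adjusted p = 0.0701), CMN replicate 6 or 13, IFS replicate 2, CCSK replicate 9, RT replicate 8, 10 or 15, or WT replicate 1. Polycomb genes were lower for 10 of 20 and higher for 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00766, adjusted p = 0.123 with an estimated correlation), such as the histone methyltransferase EZH2 (-1.43), the corepressor BCOR (-1.22) and MTF2 (-0.72, or -0.26 with adjusted p = 0.0513 as the mean of its probe sets). Proliferation genes, with the same list mean of 7.48 in CMN/IFS and CCSK, were lower for 17 of 43 and higher for 0 (same adjusted over the list alone, adjusted p = 0.0056, adjusted p = 0.753 with an estimated correlation), such as NUSAP1 (-1.38), TOP2A (-1.03, or -0.69 with adjusted p = 0.0509 without _x_at and _s_at probe sets) and CENPE (-0.91). The list mean was uneven within the class: IFS replicate 2 and CMN replicate 9 read 6.26 and 6.34, and the other 12 arrays 7.06 to 8.26. Kidney tubule markers were higher or lower for 0 of 17 genes (adjusted p = 0.648), and lymphocyte markers for 0 of 18 (adjusted p = 0.944).

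Set against RT alone, the named genes with the largest positive differences in CMN/IFS were EGFR (17.5-fold higher), TRIL (16.1-fold), SERPINE2 (15.8-fold), IFI16 (15.8-fold) and PTN (15.3-fold), while GCG, the glucagon gene, was lower (mean 5.49 against 11.17). In all, 654 genes were called, 406 higher and 248 lower in CMN/IFS. Against CCSK, MEOX2 was 35.2-fold, THBS4 28.4-fold and TGFBI 25.5-fold higher, while KIT was 12.8-fold, FGFR3 13.7-fold and the cerebellar peptide gene PCP4 71.2-fold lower; 962 genes were called, 461 higher and 501 lower. Against WT, MEOX2 was 41.7-fold and COL11A1 33.0-fold higher, while the nephron progenitor genes EYA1 and SALL1 were 33.6-fold and 32.7-fold lower; 842 genes were called, 476 higher and 366 lower. Without _x_at and _s_at probe sets and with fewer genes tested, the counts were 409, 626 and 541. Without the 2-fold minimum they were 3112, 4140 and 4145, and the share of higher genes changed from 62.1% to 42.5% against RT, from 47.9% to 54.8% against CCSK and from 56.5% to 42.1% against WT.

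RT, the tumour named in the design text, was set apart by GCG, which encodes the glucagon and GLP-1 precursor. GCG was 92.7-fold higher than in the other classes (6.53 ± 0.55 SE, adjusted p = 2.25e-14). Its mean was 11.17 ± 2.68 (SD, n = 10) in RT, 5.49 ± 2.27 (n = 14) in CMN/IFS, 4.17 ± 0.12 (n = 16) in CCSK and 4.23 ± 0.15 (n = 15) in WT. Of the RT arrays, 1 read 4.40 and the other 9 between 9.47 and 13.15; among CMN/IFS, 10 arrays read 4.04 to 4.39 and 4 read 6.42, 8.12, 9.44 and 10.72. A single probe set measured GCG. The other leading higher genes were MYOF, a membrane repair protein (9.97-fold), TNNT1, a slow muscle troponin (9.29-fold), WIF1, a secreted WNT inhibitor (8.29-fold), and MMP12, the macrophage elastase (7.76-fold). The neural transcription factor SOX11 was 17.9-fold, the phosphatase PTPRK 12.4-fold, N-cadherin (CDH2) 10.7-fold, the WNT effector LEF1 10.4-fold and TRIL 9.37-fold lower. The RT signature held 175 genes, 95 higher and 80 lower, or 93 without _x_at and _s_at probe sets.

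**Figure D4:**
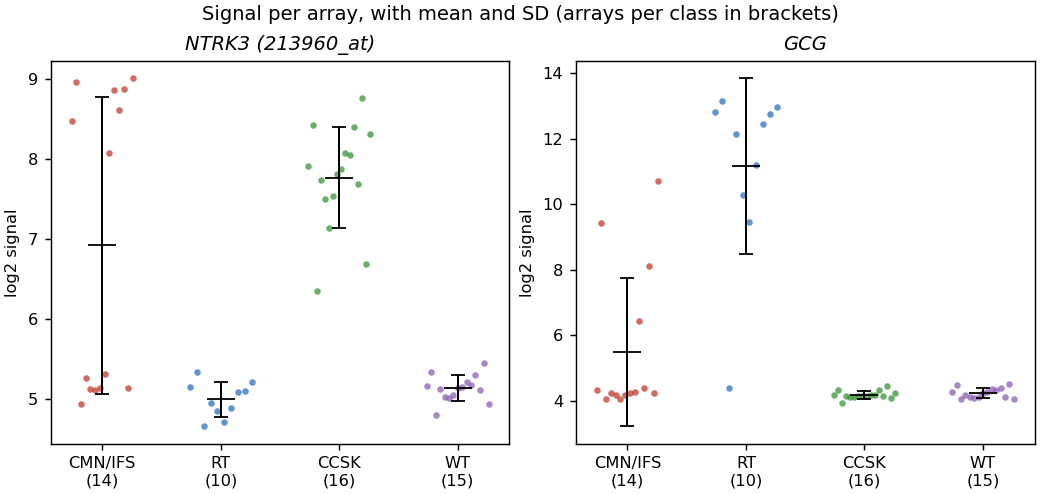
Log2 signal of NTRK3 (probe set a, with its identifier above the panel) and of GCG on each array (points), by class, with the class mean and SD as bars (n = 14, 10, 16 and 15). NTRK3 values of CMN/IFS fall between 4.94 and 5.32 or between 8.08 and 9.01, and 9 RT arrays read GCG at 9.47 or above while 1 reads 4.40.

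Several signalling and developmental groups were lower in RT. Nephron progenitor genes were lower for 16 of 20 and higher for 0 (same adjusted over the list alone, mean -1.34, camera adjusted p = 5.69e-11, and 8.95e-05 with an estimated correlation), such as DACH1 (-3.25), NCAM1 (-2.66) and SALL1 (-2.63). WNT pathway genes were lower for 13 of 31 and higher for 2 (same adjusted over the list alone, adjusted p = 0.00223, and 0.0107 with an estimated correlation); LEF1 and TCF7L1 (-1.48) were lower and the inhibitor WIF1 was higher by 3.05. Receptor tyrosine kinases were lower for 15 of 43 and higher for 4 (17 and 4 adjusted over the list alone, adjusted p = 0.00176, and 0.0295 with an estimated correlation). EGFR was at -3.23, IGF1R at -2.09 and NTRK2, the BDNF receptor, at -1.98. Their ligands were lower for 14 of 35 and higher for 2 (16 and 2 adjusted over the list alone, adjusted p = 0.00299, and 0.0304 with an estimated correlation). PTN was at -2.66 and EFNB2 at -2.12, while the vascular ligand ANGPT1 was higher by 2.18. EGFR and PTN read -0.07 (adjusted p = 0.306) and -0.01 (adjusted p = 0.961) without _x_at and _s_at probe sets. The same probe sets also differed little in CMN/IFS (0.09 and 0.04), and whether they respond to these genes was not tested.

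MAPK output genes were lower in RT for 12 of 25 and higher for 4 (13 and 4 adjusted over the list alone, adjusted p = 0.00299, adjusted p = 0.13 with an estimated correlation). The ETS factor ETV1 was at -2.17 and DUSP6 at -1.90, while MYC, the growth regulator, was higher by 1.96. The MAPK list mean was 7.28 in RT, 7.50 in WT and 7.67 in CCSK, beside the high mean of CMN/IFS (8.40). NOTCH pathway genes were lower for 8 of 16 and higher for 1 (same adjusted over the list alone, adjusted p = 0.00848, adjusted p = 0.123 with an estimated correlation). HES1 was at -1.68, NOTCH2 at -1.64 and NOTCH1 at -0.99. Hedgehog genes were lower for 4 of 10 and higher for 0 (4 and 1 adjusted over the list alone, adjusted p = 0.00832, adjusted p = 0.0541 with an estimated correlation), including FOXF1 (-1.54) and FOXF2 (-1.17), again beside the high list mean of CCSK (7.86, against 6.50 in RT, 6.51 in CMN/IFS and 6.61 in WT). GAS1 was at -1.16 (adjusted p = 0.0245). Without RT replicate 1, GAS1 read -0.82 (adjusted p = 0.123), and it also missed the test without RT replicate 3, 5, 7 or 12 and as the mean of its probe sets. TGF-beta and BMP genes were lower for 10 of 33 and higher for 4 (11 and 5 adjusted over the list alone, adjusted p = 0.0365, adjusted p = 0.215 with an estimated correlation). SMAD3 was at -1.45, SMAD7 at -1.44 and the ligand gene INHBA at 1.53. This call was lost without RT replicate 3 (adjusted p = 0.0682) or 9 (adjusted p = 0.0818). HOX genes were lower for 7 of 18 and higher for 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00303, adjusted p = 0.301 with an estimated correlation), such as HOXD4 (-1.99), HOXD11 (-1.45) and HOXD9 (-1.13). The HOX mean was 7.15 in RT and lower still in CMN/IFS (6.82). Neural genes were lower for 11 of 27 and higher for 5 (same adjusted over the list alone, adjusted p = 0.0266, adjusted p = 0.229 with an estimated correlation), with the neuronal enolase ENO2 higher by 2.60. Imprinted growth genes were lower for 6 of 13 and higher for 1 (same adjusted over the list alone, adjusted p = 0.0368, adjusted p = 0.339 with an estimated correlation). GRB10 was at -2.12, PEG10 at -1.49 and PEG3 at 1.56. The imprinted list was not called without RT replicate 3 (adjusted p = 0.0626), 5 (adjusted p = 0.0952) or 7 (adjusted p = 0.0639).

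Hypoxia genes were higher in RT for 10 of 22 and lower for 3 (same adjusted over the list alone, adjusted p = 0.0234, adjusted p = 0.583 with an estimated correlation). BNIP3, a mitophagy gene, was at 1.92, P4HA1 at 1.15 and ENO1 at 0.99. Without RT replicate 1 the hypoxia call was lost (adjusted p = 0.0684). Macrophage genes were higher for 8 of 17 and lower for 1 (9 and 1 adjusted over the list alone, adjusted p = 0.0169, adjusted p = 0.611 with an estimated correlation). CD163 was at 1.04, LAPTM5 at 0.92 and C1QA at 0.87 (0.62 without RT replicate 5, adjusted p = 0.104, and 0.75 without RT replicate 10, adjusted p = 0.0596). The macrophage call in RT was lost without RT replicate 5 (adjusted p = 0.0871), and the list mean of 7.04 lay below that of CMN/IFS (7.26). SWI/SNF subunits as a group were not called in RT: 10 of 23 were lower and 3 higher (10 and 4 adjusted over the list alone, adjusted p = 0.308).

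In CCSK, 259 genes were higher and 63 lower than in each other class. PCP4 was 64.3-fold higher (6.01 ± 0.31 SE), the LIM homeobox gene LHX2 26.8-fold (4.74 ± 0.12), the forkhead gene FOXF1 20.4-fold (4.35 ± 0.08) and the semaphorin receptor PLXNC1 19.2-fold (4.26 ± 0.14). The neurofilament gene NEFL was higher by 4.70 ± 0.19. COL6A3 (-3.17), the imprinted gene PEG3 (-2.85), SCRN1 (-2.62), S100A11 (-2.36) and the death receptor TNFRSF10B (-2.23) were lower. The CCSK signature, with 322 genes, was the largest of the 4. FGFR3 (3.73), KIT (3.42) and PDGFRA (3.10 ± 0.32) led the receptor tyrosine kinases, of which 16 of 43 were higher and 5 lower (same adjusted over the list alone, camera adjusted p = 0.00201, and 0.0295 with an estimated correlation). Their ligands were higher for 15 of 35 and lower for 6 (same adjusted over the list alone, adjusted p = 0.00116, and 0.0188 with an estimated correlation). FGF9 was at 3.58, PDGFA, a ligand of PDGFRA, at 3.38, and FGF13 at 3.22. Hedgehog genes were higher for 5 of 10 and lower for 1 (5 and 2 adjusted over the list alone, mean 1.32, adjusted p = 1.58e-06, and 6.62e-04 with an estimated correlation), with FOXF1, FOXF2 (3.74) and PTCH1 (3.48), itself a target of the pathway. WNT genes were higher for 12 of 31 and lower for 3 (12 and 4 adjusted over the list alone, adjusted p = 9.76e-04, and 0.0065 with an estimated correlation). LEF1 was at 2.56, WNT5A at 2.36 and WNT5B at 2.28.

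HOX genes were higher in CCSK for 13 of 18 and lower for 2 (14 and 2 adjusted over the list alone, mean 0.86, adjusted p = 1.56e-06, adjusted p = 0.0541 with an estimated correlation). HOXB6 was at 2.25, HOXB7 at 1.95 and HOXC6 at 1.73. Neural genes were higher for 12 of 27 and lower for 3 (same adjusted over the list alone, adjusted p = 0.0065, adjusted p = 0.123 with an estimated correlation), with NEFL, NRCAM (3.48) and NEFM (3.44). NOTCH genes were higher for 7 of 16 and lower for 2 (same adjusted over the list alone, adjusted p = 0.0404, adjusted p = 0.243 with an estimated correlation). The ligands JAG1 and JAG2 were at 1.74 and 1.499 and the receptor NOTCH2 at 1.23. This call was lost without CCSK replicate 5 (adjusted p = 0.0547), 6 (adjusted p = 0.0514) or 9 (adjusted p = 0.0518). Proliferation genes were lower for 22 of 43 and higher for 1 (same adjusted over the list alone, adjusted p = 0.0167, adjusted p = 0.779 with an estimated correlation); RRM2 (-1.16) and PTTG1 (-1.05) were lower, and CENPE, a mitotic motor, was the 1 higher gene (1.91). RRM2 read -0.51 (adjusted p = 0.0686) without _x_at and _s_at probe sets. The proliferation list mean was uneven within CCSK: 8 arrays read 6.88 to 7.25 and the other 8 read 7.65 to 8.15, next to a class mean of 7.89 in RT. Macrophage genes were lower for 14 of 17 and higher for 0 (same adjusted over the list alone, adjusted p = 0.00214, adjusted p = 0.536 with an estimated correlation). CD74 and CD163 were both at -1.18 and C1QB at -1.10. The macrophage mean was 6.18 in CCSK and 6.25 in WT, and higher in the 2 other classes.

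WT was set apart by genes of the nephron progenitor. EYA1, a coactivator needed for kidney formation, was 30.6-fold higher (4.93 ± 0.12 SE), followed by ADGRG2 (26.4-fold), LYPD1 (18.1-fold), the hyaluronan synthase HAS2 (12.6-fold) and WASF3 (12.2-fold). The collagens COL5A2 (-3.69), COL3A1 (-3.13) and COL1A2 (-3.01), the transcription factor NFIB (-2.81) and ITM2A (-2.53) were lower. The WT signature held 131 genes, 92 higher and 39 lower. Nephron progenitor genes were higher for 17 of 20 and lower for 1 (same adjusted over the list alone, mean 2.08, camera adjusted p = 1.36e-17, and 7.11e-07 with an estimated correlation). Epithelial genes were higher for 10 of 15 and lower for 0 (same adjusted over the list alone, adjusted p = 9.83e-05, adjusted p = 0.147 with an estimated correlation), with the adhesion molecules EPCAM (2.98) and CD24 (2.11) and the keratin KRT18 (2.01). WT replicate 14 stood apart on this list, at 8.28 with the other 14 arrays at 6.19 to 7.19, and on kidney tubule genes, at 7.07 with the others at 6.16 to 6.51.

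Lists of proliferation, SWI/SNF, polycomb and HOX genes were higher in WT than in the mean of the other classes. Proliferation genes were higher for 25 of 43 and lower for 0 (33 and 0 adjusted over the list alone, mean 0.54, adjusted p = 2.54e-05, adjusted p = 0.589 with an estimated correlation). MCM2 was at 1.40, CENPF at 1.36 and MCM7 at 1.27. The list mean was 7.31 to 7.59 on 3 WT arrays, below the RT class mean of 7.89, and 8.03 to 8.64 on the other 12. SWI/SNF subunits were higher for 13 of 23 and lower for 1 (same adjusted over the list alone, adjusted p = 0.00223, adjusted p = 0.231 with an estimated correlation). SMARCC1 was at 1.06 and SMARCB1 at 0.98, and SMARCA2 lower at -1.08. Polycomb genes were higher for 10 of 20 and lower for 1 (same adjusted over the list alone, adjusted p = 0.0086, adjusted p = 0.123 with an estimated correlation). JARID2 was at 1.62, EZH2 at 0.90 and RBBP4 at 0.73. HOX genes were higher for 7 of 18 and lower for 0 (same adjusted over the list alone, adjusted p = 0.00642, adjusted p = 0.339 with an estimated correlation). HOXD4 was at 1.87, HOXD11 at 1.73 and HOXD1 at 1.27. The HOX mean of WT (7.90) lay below that of CCSK (8.15). CDK inhibitors and checkpoint genes were lower for 11 of 18 and higher for 0 (same adjusted over the list alone, adjusted p = 3.04e-04, and 0.0295 with an estimated correlation). CDKN1A, which encodes p21, was at -0.92, GADD45A at -1.18 and the cyclin gene CCND1, which drives the cycle, at -1.52.

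Lists of matrix, hedgehog, MAPK, immediate early, macrophage and interferon response genes were lower in WT than in the mean of the other classes. Collagen matrix genes were lower for 28 of 39 and higher for 1 (29 and 1 adjusted over the list alone, mean -1.08, adjusted p = 1.93e-09, adjusted p = 0.091 with an estimated correlation). POSTN was at -3.08. Matrix proteases and inhibitors were lower for 10 of 19 and higher for 1 (11 and 1 adjusted over the list alone, adjusted p = 5.77e-04, and 0.026 with an estimated correlation). SERPINF1 was at -2.78, CTSK at -1.82 and MMP9 at -1.42. Hedgehog genes were lower for 5 of 10 and higher for 2 (same adjusted over the list alone, adjusted p = 0.00375, and 0.0356 with an estimated correlation). PTCH1 was at -1.92, FOXF1 at -1.39 and GAS1 at 1.92. The WT mean of this list (6.61) was above those of CMN/IFS (6.51) and RT (6.50), so the call came from CCSK (7.86), and without RT replicate 15 adjusted p = 0.0545 with an estimated correlation. MAPK output genes were lower for 10 of 25 and higher for 5 (11 and 5 adjusted over the list alone, adjusted p = 0.00848, adjusted p = 0.215 with an estimated correlation). MYC was at -1.93, EGR1 at -1.65 and HMGA2 at 2.29. The MAPK mean of WT (7.50) lay between those of RT (7.28) and CCSK (7.67), so the call came from CMN/IFS (8.40). Immediate early genes were lower for 12 of 18 and higher for 1 (12 and 2 adjusted over the list alone, adjusted p = 3.81e-04, adjusted p = 0.229 with an estimated correlation). KLF4 was at -1.68 and FOS at -1.30. Macrophage genes were lower for 14 of 17 and higher for 1 (same adjusted over the list alone, adjusted p = 1.34e-04, adjusted p = 0.385 with an estimated correlation). LYZ was at -1.11, CD163 at -1.05 and C1QA at -0.95. Interferon response genes were lower for 11 of 22 and higher for 1 (13 and 1 adjusted over the list alone, adjusted p = 0.0015, adjusted p = 0.589 with an estimated correlation). ISG15 was at -2.26, IFI44 at -1.43 and BST2 at 1.74.

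**Figure D5:**
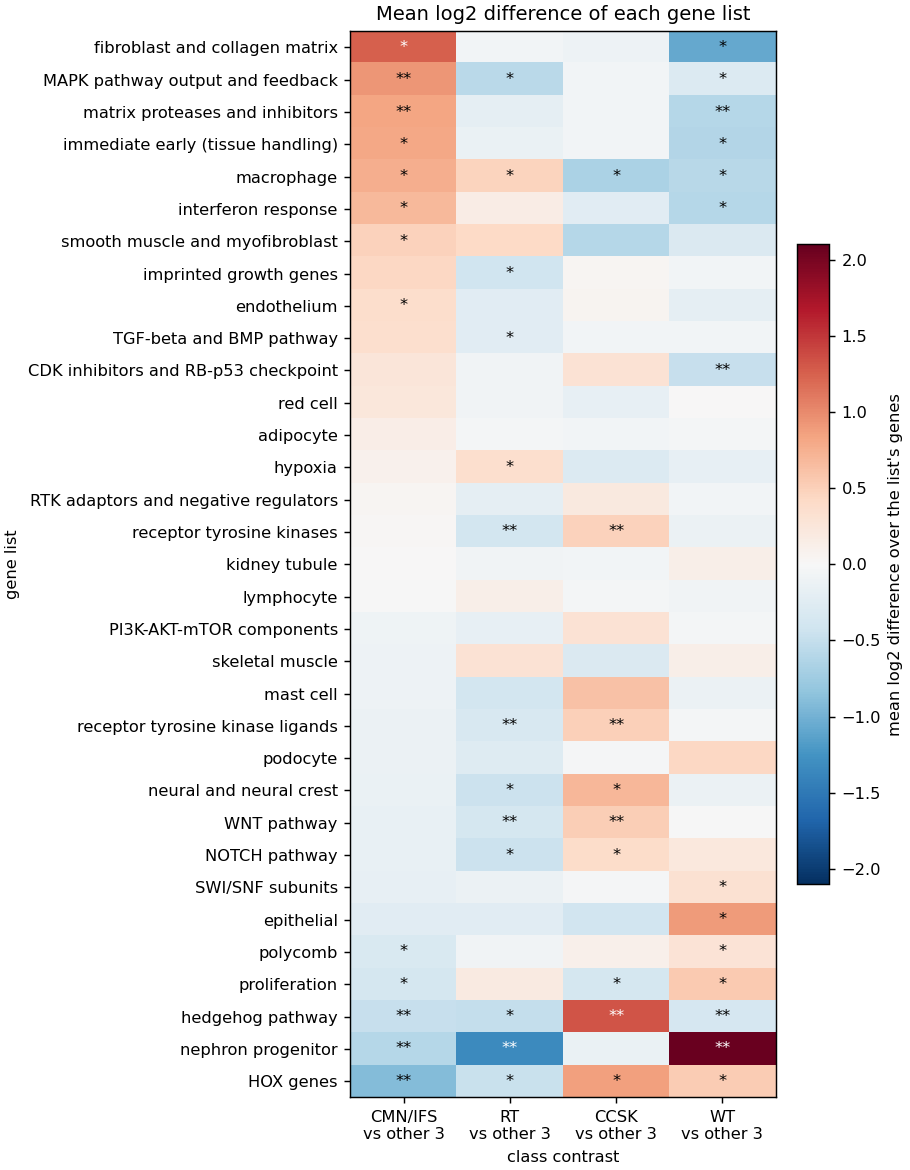
Mean log2 difference of each of 33 gene lists (vertical axis) in each class against the mean of the other 3 classes (horizontal axis), as colour from blue (lower) to red (higher). An asterisk marks a list called by camera with the preset correlation and a double asterisk one also called with an estimated correlation; the largest mean is 2.08, for nephron progenitor genes in WT.

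IFS and CMN, the tumours joined in the CMN/IFS class, differed in few single genes. SCRG1 was higher in the 2 IFS arrays than in the 12 CMN arrays by 1.70 ± 0.30 SE, the proteoglycan gene CSPG4 by 1.62 ± 0.30 and CD70, a ligand of the TNF family, by 1.33 ± 0.24 (each with adjusted p = 0.00434), and the matrix gene FBLN2 by 1.21 ± 0.26 (adjusted p = 0.048). These 4 were all the genes called; 572 of 10324 genes had an unadjusted p below 0.05, where 516 would with no difference at all. Without IFS replicate 2, SCRG1 read 0.77, CD70 0.21 and FBLN2 0.70 (adjusted p = 1 for each) and CSPG4 1.59 (adjusted p = 0.342). Without IFS replicate 3, CSPG4 read 1.64 (adjusted p = 0.0605), and FBLN2 missed the test without many of the other arrays too, with adjusted p up to 0.0818. As the mean of its probe sets CSPG4 read 0.94 (adjusted p = 0.199). Under that setting the FBLN2 value was unchanged at 1.21, but it missed the test (adjusted p = 0.062). With the replicate number as a block CSPG4 read 1.66 and CD70 1.26 (adjusted p = 0.126 for each) and FBLN2 1.26 (adjusted p = 0.205). The count was 1 without IFS replicate 2 and 26 without IFS replicate 3, 0 with only the 14 arrays in the fit, and 2 with the replicate number as a block.

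Camera called 8 gene lists between IFS and CMN, and 6 of these calls were lost without 1 of the 2 IFS arrays. Counts adjusted over the list alone were the same unless given. Proliferation genes had a mean difference of -0.63 in IFS against CMN, with 0 of 43 past the test alone (adjusted p = 1.93e-09, adjusted p = 0.406 with an estimated correlation). This came from IFS replicate 2: the mean was 0.0509 (adjusted p = 0.353) without it and -1.31 without IFS replicate 3. Immediate early genes had a mean of 0.35, with 0 of 18 past the test and 2 higher adjusted over the list alone (adjusted p = 0.00299, adjusted p = 0.339 with an estimated correlation). Without IFS replicate 2 it was -0.0620 (adjusted p = 0.898), and 0.75 without IFS replicate 3. Hypoxia genes had a mean of 0.18 with 0 of 22 past the test (adjusted p = 0.0249, adjusted p = 0.583 with an estimated correlation). Here IFS replicate 3 carried the difference, with -0.0475 (adjusted p = 0.976) without it and 0.41 without IFS replicate 2, and the call was also lost without CMN replicate 4, 8 or 9 (adjusted p up to 0.0675). MAPK output genes had a mean of 0.16 with 0 of 25 past the test (adjusted p = 0.0355, adjusted p = 0.333 with an estimated correlation). The value without IFS replicate 2 was 0.11 (adjusted p = 0.349), and CMN replicate 7 also ended the call when left out (adjusted p = 0.0532). Matrix proteases had a mean of 0.28 with 0 of 19 past the test (adjusted p = 0.0404, adjusted p = 0.221 with an estimated correlation), which was 0.14 (adjusted p = 0.673) without IFS replicate 2 and 0.43 without IFS replicate 3. That call was also lost without CMN replicate 4, 5, 6 or 8 (adjusted p up to 0.0811). Lymphocyte genes had a mean of -0.22 with 0 of 18 past the test (adjusted p = 0.00859, adjusted p = 0.583 with an estimated correlation), or -0.18 (adjusted p = 0.159) without IFS replicate 3.

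The other 2 list calls between IFS and CMN held with either IFS array left out. Collagen matrix genes had a mean of 0.53, with FBLN2 the 1 higher of 39 (adjusted p = 9.51e-07, adjusted p = 0.168 with an estimated correlation), and 0.34 (adjusted p = 0.00952) without IFS replicate 2. CDK inhibitors and checkpoint genes had a mean of 0.46, with 0 of 18 past the test (adjusted p = 2.05e-05, and 0.0065 with an estimated correlation). Without IFS replicate 2 their mean was 0.33 (adjusted p = 0.00444, adjusted p = 0.0654 with an estimated correlation). Over all 5 contrasts, camera called 57 of 165 list tests with the preset correlation and 18 with an estimated one, while fry, which asks only whether a list moves on balance, called 77.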

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

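The tests of NTRK3, GCG and MAPK genes in this part were chosen only after these patterns had been seen in the data; what each test would show was written down before its value was computed. The comparisons of array groupings were planned.

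In RT, single arrays stood apart from the other 9 for some genes. Each of 203 results was checked in the 10 RT arrays for an extreme array whose gap to its neighbour was a large share of the group's range, and 21 stood out; about 1 in 20 groups does so by chance. The gap took a share of 0.907 of the range for CDH2, with 1 array at 10.32 and the next at 6.82, 0.899 for PTGS2 (8.31, next 4.35), 0.838 for WT1 (9.57, next 5.05) and 0.830 for FGF13 (7.94, next 5.64). High single arrays also gave shares of 0.619 for PLXNC1 (6.86, next 5.50), 0.527 for PTTG1 (11.78, next 10.14), 0.526 for TNC (8.71, next 7.06), 0.510 for CSPG4 (6.66, next 5.90) and 0.506 for NEFL (6.95, next 5.56). Smaller shares on the high side were 0.497 for NEFM, 0.494 for CSRP1, 0.494 for EPCAM, 0.489 for NTRK2, 0.487 for CD70, 0.478 for ODC1 and 0.474 for ENG. On the low side the share was 0.678 for CALD1 (6.29, next 8.75), 0.579 for GCG (4.40, next 9.47), 0.533 for MYC (7.65, next 8.73), 0.548 for the mean of the collagen matrix genes (6.97, next 7.88) and 0.477 for the mean of the red cell genes (6.01, next 6.22).

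Other groupings of the arrays gave fewer genes than the tumour classes did. Only 1 of 100 splits, the real one, reached the count of CMN/IFS against RT (654 genes, highest other split 247), against CCSK (962, highest other 242) and against WT (842, highest other 192). The same held for the signatures of CMN/IFS (189, highest other 0), RT (175, highest other 42), CCSK (322, highest other 0) and WT (131, highest other 0), with 1 of 100 splits each. That is the smallest share that 100 splits can give. At this limit the splits argue against a random grouping of the arrays as the source of these counts. For IFS against CMN, 47 of the 91 splits of the 14 arrays gave at least 4 genes and the highest other split gave 150, so chance cannot be excluded. A split with several times the real count can mark a structure among the 14 arrays other than the IFS and CMN labels, but genes that vary together also raise the highest of many splits, and no test here tells these apart.

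NTRK3 fell into separate groups of values within CMN/IFS, 4.94 to 5.32 on 7 arrays and 8.08 to 9.01 on the other 7 for probe set a. A fault of that probe set is argued against, since the 7 highest arrays were the same 7 on the separate probe set c (7 of 7 shared; 4.01 to 4.35 and 7.01 to 8.16 there). Tumours of another class under a wrong label are argued against, since all 14 of the 14 arrays had a held-out CMN/IFS score above every other array (lowest 0.846, highest elsewhere -0.06). Of the 7 lowest arrays, 3 were among the 7 with the smallest SD, which argues against a narrow spread of array values as the cause. The SD is not a direct measure of RNA quality, so poor RNA stays open. Transcript variants read differently by the probe sets stay open, and the ETV6-NTRK3 fusion, which could raise signal from the kinase end of NTRK3 in the tumours that carry it, is an untested hypothesis, as fusion status was not analysed here. The design gives no group for it, so no biological explanation was tested.

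GCG was bright on 9 of 10 RT arrays. Pancreas or gut tissue in the specimens is argued against, because 22 other marker genes of these tissues had a median log2 difference of -0.0250 in RT (highest 0.128, 0 higher, 0 lower), including the insulin gene INS (-0.03) and PRSS2, an abundant pancreatic enzyme (-0.13). A wrong label for the 1 RT array without GCG is argued against, because 10 of the 10 RT arrays, this one included, had a held-out RT score above every other array (lowest 1.03, highest elsewhere 0.0286). Cross-hybridisation of another transcript to the only GCG probe set stays open, since no second probe set could test it, as does expression of GCG by the tumour cells, which may differ between RT and the other classes for a reason not tested here.

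MAPK output genes were higher in CMN/IFS together with immediate early and macrophage genes. Over the 23 MAPK genes outside the immediate early list, the median difference was 0.510. With the immediate early mean as a covariate it was 0.349 (p = 0.0114 by camera with an estimated correlation). CMN replicate 5 stood apart on the immediate early mean, and the fit was not repeated without it, so the adjustment may be too small. The CMN/IFS array lowest on both full lists, CMN replicate 6, read 7.14 for immediate early genes, as did the RT class mean. Its MAPK mean of 8.15 was above every array of the other classes (highest 7.91, in CCSK). Tissue handling as the whole cause is thus argued against, though it may account for part. The covariate could also remove biology because MAPK signalling itself drives immediate early genes. With the macrophage mean as a covariate the median was 0.571 (p = 0.0027), which argues against macrophages as the cause. Stronger receptor tyrosine kinase signalling, named by the study's title, is a candidate explanation that stays open, as does the fibroblast content of the tissue, since neither was tested here.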

How the results depend on the processing

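The covariate fits, the fit without the array of smallest SD the split of CMN/IFS into 3 sets and the gene lists with each array left out were chosen only after the results were seen; the other settings were planned. Of 14257 gene results under alternatives (211 results on 170 named genes), 14182 kept their direction and their side of the threshold. In the same direction 74 lost the call, and 0 gained one. The 1 that reversed was FGFR2 in CMN/IFS, at 0.0031 without _x_at and _s_at probe sets, where a dim probe set took the place of the bright one. Most of these results came from fits with 1 array left out (11553 kept, 52 lost the call), which share nearly all arrays with the main fit. Without _x_at and _s_at probe sets 123 kept, 7 lost the call and 1 reversed, and genes left with no probe set were not counted. Most named genes were picked for large differences in these data, so these counts do not describe genes picked otherwise.

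Without _x_at and _s_at probe sets, which left fewer genes to test, the counts were 409 for CMN/IFS against RT, 626 against CCSK, 541 against WT, 121 for the CMN/IFS signature and 93 for the RT signature. With no fold minimum the pairwise counts were 3112, 4140 and 4145, and the signatures of CMN/IFS, RT, CCSK and WT held 956, 955, 1404 and 1018 genes, by construction of the threshold; the share of higher genes in the signatures was then 57.1%, 71.5%, 50% and 75.2%, against 85.2%, 54.3%, 80.4% and 70.2% with it. For IFS against CMN the count was 2 with the dim filter at the median, 2 with the mean of all probe sets, 9 with array weights and 0 with only the groups compared in the fit; the cause was not tested. Of 57 called gene lists, 18 were called with an estimated correlation. The preset was 0.01, and camera gives larger p-values for a larger correlation. In CMN/IFS the estimate was 0.205 for collagen matrix genes, which lost the call. It was 0.0388 for matrix proteases, which kept it. With single arrays left out, 53 to 59 lists were called, or 16 to 21 with an estimated correlation. With an estimated correlation, collagen matrix genes in CMN/IFS gained the call without 1 of 7 arrays, HOX genes in CCSK without 1 of 6 and hedgehog genes in RT without 1 of 6. For IFS against CMN, the macrophage list (-0.71, adjusted p = 1.17e-04) gained the call without IFS replicate 2, smooth muscle genes without IFS replicate 3 or CMN replicate 3, and imprinted genes without 1 of 14 arrays. The mast cell and smooth muscle lists in CCSK and the endothelial and hypoxia lists in WT also gained the call with 1 array left out.

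With the replicate number as a block (replicate block) the count for IFS against CMN was 2, with 1 gene higher and 1 lower. The other counts (676, 956 and 836 pairwise, and 183, 191, 318 and 124 for the signatures) stayed within 1.5 times those of the main fit. Same-numbered arrays correlated above 0.1 in 24 of 67 pairs. That share was not computed for other pairs, so it does not decide whether the numbers pair the arrays. With single arrays left out, the counts ran from 629 to 687 against RT, 946 to 990 against CCSK, 816 to 876 against WT, 181 to 203, 166 to 193, 314 to 333 and 122 to 140 for the 4 signatures, and 1 (without IFS replicate 2) to 26 (without IFS replicate 3) for IFS against CMN.

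Among the added fits, the CMN/IFS signature held 193 genes with array SD as a covariate, 180 with the immediate early mean (153 shared), 149 with the macrophage mean (134 shared), 187 without the array of smallest SD and 150 with CMN/IFS in 3 sets (139 shared). Alternatives with other pseudocounts were not run because the values were already logarithms, and the 3′ to 5′ covariate was not run because the table used holds 0 control probe sets. The number of arrays limits precision most for the 2 IFS arrays, and genes near the floor of the signal are read least well.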

Other observations

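Camera did not call the gene lists of this paragraph in CMN/IFS, although members of many passed the test singly, in both directions. Single passes were common among all genes: with no fold minimum, 3112 to 4145 of 10324 passed in the pairwise comparisons of CMN/IFS. The share for the contrast used in this paragraph is not given here. Counts adjusted over the list alone were the same unless given. Podocyte genes were higher for 3 of 11 and lower for 5 (camera adjusted p = 0.76), epithelial genes higher for 1 of 15 and lower for 5 (0.324), skeletal muscle genes higher for 1 of 11 and lower for 2 (1 and 1 adjusted over the list alone, 0.823), neural genes higher for 3 of 27 and lower for 7 (0.593) and SWI/SNF subunits higher for 4 of 23 and lower for 7 (0.327). TGF-beta and BMP genes were higher for 10 of 33 and lower for 5 (10 and 6 adjusted over the list alone, adjusted p = 0.114), CDK inhibitors and checkpoint genes higher for 6 of 18 and lower for 2 (0.076), hypoxia genes higher for 6 of 22 and lower for 0 (4 and 0 over the list alone, 0.342), WNT genes higher for 3 of 31 and lower for 8 (0.288), NOTCH genes higher for 1 of 16 and lower for 3 (0 and 2 over the list alone, 0.423) and imprinted growth genes higher for 2 of 13 and lower for 2 (0.531). Adipocyte (2 of 8 higher, 1 over the list alone, adjusted p = 0.398), red cell (1 of 8 higher, 0.275) and mast cell genes (1 higher and 1 lower of 6, 0.992) were not called either. Fry, which tests a list against no change and not against other genes, did call WNT (adjusted p = 7.41e-06), TGF-beta and BMP (1.07e-05), CDK inhibitor (4.54e-05), NOTCH (0.00853) and SWI/SNF genes (0.0141).

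NTRK3 was read above RT and WT in CCSK on each of the 3 plain _at probe sets. On probe set a the CCSK mean was 7.77 ± 0.64 (SD, n = 16), against 4.997 ± 0.22 (n = 10) in RT and 5.14 ± 0.16 (n = 15) in WT, and on c it was 6.85 ± 0.74 against 4.11 ± 0.07 and 4.22 ± 0.15. CMN/IFS had means of 6.93 ± 1.86 on a and 5.84 ± 1.76 on c, over arrays in separate groups of values. The upper 7 CMN/IFS arrays, at 8.08 to 9.01 on a and 7.01 to 8.16 on c, all read above the CCSK mean. On b, CCSK read 7.27 ± 0.24 while CMN/IFS read 5.94 ± 0.31, RT 5.87 ± 0.25 and WT 5.93 ± 0.23. The widest gap among the CMN/IFS arrays was 0.355 on b, against 2.77 on a and 2.66 on c. It also lay above 7 arrays on the _s_at probe set (5.01 below, 6.12 above) and, with a width of 0.364, on an _x_at probe set. On the remaining _x_at probe sets it lay above 12 arrays. Whether the same 7 arrays were parted on these further probe sets was not compared. These probe sets of NTRK3 were looked at only after the values of the first had been seen.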
